A study of Arabidopsis thaliana with 24 samples.

How the data were processed

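RNA from roots and shoots of WT and oas-a1.1 plants, untreated or given cadmium chloride, was measured on Affymetrix ATH1 arrays, 24 arrays in 8 groups of 3. The authors deposited log2 values made with RMA, which corrects background, normalizes arrays by quantiles and summarises each probe set; their notes name the affy package, and the versions of RMA and affy are not given in the sources used here. Whether all arrays were normalized together is not stated. Values were used as deposited, and each of the 24 columns was matched to its sample label, with 0 columns left over. Groups and replicate numbers came from the labels. Roots were treated for 18 h and shoots for 24 h, so organ and hours cannot be separated, and cadmium responses were not compared between organs. The time of day of the untreated harvest is not stated in the labels. The 64 control probe sets were left out of the tests and 22746 were kept, with no filter on level. Gene names came from the annotation of the probe sets supplied with the series, in which 13513 probe sets have a single gene, 503 have several and 8730 have none; 13436 of the 13513 were matched to a reference gene table, and 77 were not. Genes are named only where the probe set has a single gene, and probe sets ending in s_at or x_at, such as that of PDF1.2b, can bind related transcripts.

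Each organ was fitted by itself with limma 3.58.1 in R 4.3.3, as a model with a mean for each of its 4 groups over its 12 arrays, moderated by empirical Bayes. From it came mutant against WT in each treatment, cadmium against untreated in each genotype, and the interaction of genotype and cadmium. The mutant effect in untreated roots was compared with that in untreated shoots in a model of all 24 arrays. All tests were two-sided, p values were adjusted by Benjamini and Hochberg within a comparison, and an adjusted p under 0.05 was called; at least 2-fold means an absolute log2 difference of 1 or more. A standard deviation describes the 3 arrays of a group, and a standard error comes from the limma model. Tests, comparisons, gene lists and the rule for naming genes were set before the data were examined. The rule took OASA1, the 6 largest rises and falls that passed and whose groups did not overlap (for interactions, that passed), up to 3 members with the smallest p of each called list or of the 5 lists with the smallest p, and the sulfate and cysteine lists. A gene named in a comparison may have its value given in others, and members of the added families in the closing text were picked by their size of change after the values were seen.

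Gene lists were tested with camera at a fixed correlation of 0.01 between genes, adjusted over the lists of a comparison; camera with an estimated correlation and fry were run beside it. Of 24 lists written beforehand, 12 had at least 3 measured members and were tested. Measured means a probe set with a single named gene, which 71 of the 477 entries had. The rest may lie among the 8730 probe sets with no gene listed, so a list result covers its named members only. For sulfate assimilation these were APS3, APS4 and SIR, with no APR or SULTR gene. For superoxide, peroxide and ascorbate enzymes they were SAPX, TAPX and ATMDAR2, with no superoxide dismutase or catalase. The cysteine synthesis, ferritin, indolic glucosinolate, ethylene and aquaporin lists had no named member here and were not analysed. A further 22 gene families, defined by symbol, were fixed after the names of the measured genes had been seen but before any test, and appear only in the closing text. A short list of clock-regulated genes was written after the values of COR27 had been seen.

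Alternatives planned beforehand were the upper 60% of probe sets by mean level, centring of each array on its median, quantile normalization again, a model of all 24 arrays, a model of the compared arrays alone, a trended and robust prior, array weights, replicate number as a block, and each array left out in turn. Added later were the level of a 25S ribosomal RNA control as a covariate, only arrays with that level at or above 7 on the log2 scale (a boundary set after the values were seen), each replicate number left out in all groups, and list and family calls without each array. After the results had been seen, checks were added: shoot counts with matching arrays left out of both contrasts, plastid-encoded medians under both 25S settings, the interaction contrast of each split on the first principal components, and sign changes of named values and of the balance of higher and lower calls. Replicate numbers were checked as pairs by correlating residuals of arrays with the same number. Only mutant against WT roots under cadmium had all correlations above 0.1, from 0.11 to 0.64, so its blocked value is given in the report. In the remaining root comparisons replicates 1 and 3 correlated at 0.39 to 0.60 and replicate 2 at -0.15 to 0.02. Pairing is therefore not excluded there, and their blocked counts are given in the closing text. The number of calls was also counted over other splits of the arrays, with a random seed of 1. The procedure was tested on simulated data: for the root design it recovered 22.4%, 74.6% and 98.5% of 67, 67 and 66 probe sets changed by 0.5, 1 and 2 log2 units, with 6 false calls among 22546 unchanged ones. For the shoot design it recovered 34.3%, 79.1% and 97.0%, with 4 false calls. The simulated noise was independent between probe sets and arrays, with no 25S split and no replicate effect, so these rates may not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw array files were not used here.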

Results

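Gene expression was measured in roots and shoots of Arabidopsis thaliana, in the wild type (WT, accession Col-0) and in oas-a1.1, a mutant in OASA1, the cytosolic enzyme that makes cysteine from O-acetylserine and sulfide. Plants grown in hydroponic culture were left untreated or given cadmium chloride, for 18 h before roots were taken and for 24 h before shoots were taken. The labels give the cadmium dose as 50 µM in the series design and as 50 mM in the sample protocols, so the dose is uncertain here. Each combination of tissue, genotype and treatment had 3 biological replicates, each on its own ATH1 array, which made 8 groups and 24 arrays. The values are log2 RMA values, and 22746 probe sets were tested after 64 control probe sets were left out. A single gene was listed for 13513 of these, several genes for 503 and no gene for 8730. The number of arrays, 3 per group, limits the precision of every value. Within a group the arrays correlated across probe sets at 0.971 to 0.993, against 0.721 to 0.758 between root and shoot arrays; probe sets are not independent replicates.

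OASA1 itself was not named in the annotation used here, so the mutated gene was not read by name. The largest fall in each of the 4 mutant against WT comparisons was in the same probe set, which has no name in that annotation and was singled out after its values were seen. Its log2 values lay between 10.48 and 12.28 on the 12 WT arrays and between 4.05 and 4.51 on the 12 mutant arrays, and the lowest value of any probe set on the 24 arrays was 3.27. Its difference was -6.73 ± 0.19 (SE) log2 units in untreated roots (n = 3 and 3 arrays, adjusted p = 1.3e-08, limma) and -7.35 ± 0.25 in untreated shoots (adjusted p = 2.0e-07, limma). It was -6.27 in roots and -6.49 in shoots under cadmium, with adjusted p of 3.0e-08 and 8.0e-07. Whether the mutant arrays read above background was not tested, so these differences may understate the fall.

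A control probe set for 25S ribosomal RNA split the arrays in a way the groups do not explain. It read 4.62 to 6.0 on 8 arrays, 6 of them numbered replicate 1, and 7.72 to 11.96 on the other 16. Untreated WT shoots and cadmium-treated mutant shoots each held 2 of the 8 low arrays. Cadmium-treated WT roots, both groups of mutant roots and cadmium-treated WT shoots held 1 each, and untreated WT roots and untreated mutant shoots held none. Counts with this level as a covariate, and on high arrays alone, stand beside the main counts. In shoots the high arrays left a single array in untreated WT and a single array in the cadmium-treated mutant, so counts on high arrays in shoots and between organs say nothing about the stability of a call.

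**Figure D1:**
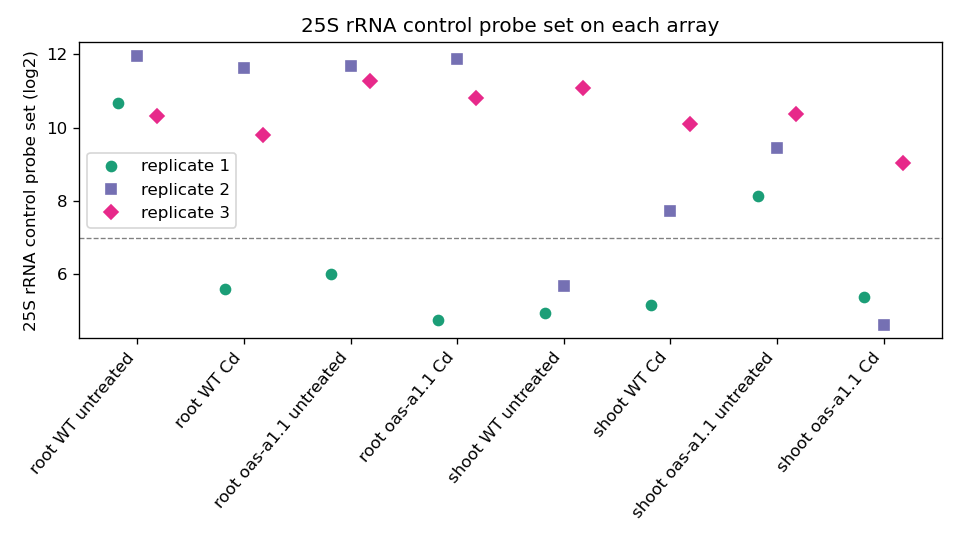
Level of the 25S ribosomal RNA control probe set (log2, y axis) on each array, by group (x axis), with a marker for each replicate and a dashed line at 7. The 8 arrays under the line read 4.62 to 6.0 and the 16 above it 7.72 to 11.96.

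In untreated roots, the comparison of mutant with WT asks what the loss of OASA1 changes without cadmium. QQS, a gene that acts on starch content, read 6.64 ± 0.39 (SD, n = 3) in the mutant and 4.62 ± 0.30 in WT, a rise of 2.02 ± 0.23 (SE) log2 units (adjusted p = 0.00435, limma). AT2G36690, of the oxoglutarate-dependent dioxygenase family, rose by 2.11 ± 0.20 (adjusted p = 0.0023), and AT3G07090 rose by 1.39 ± 0.18 (adjusted p = 0.0107). AT4G33980, a relative of the cold-regulated COR27, fell by 1.56 ± 0.20 (adjusted p = 0.00797), and AT1G76590, of the PLATZ zinc-binding family, fell by 1.64 ± 0.24 (adjusted p = 0.0183). The calls of QQS and AT2G36690 held without any single array. That of AT4G33980 was lost without WT replicate 1, that of AT3G07090 without WT replicate 2, and that of AT1G76590 without mutant replicate 2 or 3 or WT replicate 1 or 2. A fit of the 6 arrays alone also ended the calls of AT3G07090 and AT1G76590. Among the gene lists, superoxide, peroxide and ascorbate enzymes shifted upward (median 0.42 over 3 members, adjusted p = 0.0105, camera), with adjusted p = 0.357 with an estimated correlation. Its members were SAPX at 0.45, TAPX at 0.42 and ATMDAR2 at 0.20; 0 of the 3 passed over all probe sets and 2 passed adjusted over the list alone. Its call was lost without mutant replicate 2 or WT replicate 3. SAPX and TAPX are chloroplast enzymes, and in the same arrays the 8 photosynthesis genes had a median of 0.31 (adjusted p = 0.113) and the 3 root markers a median of -0.28 (adjusted p = 0.328), neither past the threshold. The heat shock list also shifted upward (6 of 8 members positive, median 0.32, adjusted p = 0.0204), again with adjusted p = 0.357 with an estimated correlation. None of its members passed over all probe sets and 1 passed adjusted over the list alone; the co-chaperone AT2G20560 read 1.2 higher with adjusted p = 0.178. That call was lost without mutant replicate 2 or 3 or WT replicate 1. Of the sulfate assimilation list only 3 genes had a named probe set. The ATP sulfurylases APS3 and APS4 read -0.62 and 0.70 and the sulfite reductase SIR 0.01, none past the threshold, and the rest of the list was not read. In all, 81 probe sets passed an adjusted p of 0.05, 37 higher and 44 lower, of which 25 and 32 changed at least 2-fold. Leaving out an array gave 138 without mutant replicate 1, 38 without mutant replicate 2, 24 without mutant replicate 3, 21 without WT replicate 1 and 17 without WT replicate 2. More were higher than lower in each of these 5 (73 and 65, 20 and 18, 14 and 10, 14 and 7, 9 and 8), against 25 and 52 without WT replicate 3, so the balance is not settled. With the 25S level as a covariate the count was 89, and on high arrays alone 124.

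Cadmium in WT roots, against untreated WT roots, shows the response of the normal root at 18 h. Glutathione reductase, GR1, rose by 2.17 ± 0.13 (SE) log2 units, from 7.38 ± 0.06 (SD, n = 3) to 9.55 ± 0.22 (adjusted p = 8.5e-06, limma). AT1G47400, a small peptide gene induced under iron deficiency, rose by 2.08 ± 0.26 (adjusted p = 0.00123). The carnitine transporter gene OCT1 rose by 2.68 ± 0.23 and the peroxidase gene AT4G36430 by 2.87 ± 0.29. COR27, a cold-regulated gene that acts on the circadian clock, fell by 3.51 ± 0.19, from 7.87 ± 0.36 to 4.36 ± 0.13 (adjusted p = 6.5e-06). AT5G62360, of the pectin methylesterase inhibitor family, fell by 4.47 ± 0.30, AT4G33980 by 2.92 ± 0.20 and the peroxidase gene AT5G39580 by 3.19 ± 0.55. These calls held without any single array. Of 12 glutathione S-transferases, 3 rose and none fell: GSTU27 rose by 1.06 and ATGSTF13 by 0.97 in every leave-out, while the rise of GSTU18 by 0.49 held only without cadmium-treated replicate 1. That list shifted upward (median 0.14, adjusted p = 0.0141; adjusted p = 0.193 with an estimated correlation), a call lost without cadmium-treated replicate 1 or untreated replicate 3. All 8 heat shock genes read higher (median 0.45, adjusted p = 0.0141; adjusted p = 0.198 with an estimated correlation), and 1 passed, AT2G20560, which rose by 1.60 and lost its call without untreated replicate 1. Of 3 abscisic acid and dehydration genes, the dehydrin genes LTI30 and COR47 fell by 1.94 and 0.78, while COR15A read -0.02. That list shifted downward (median -0.78, adjusted p = 0.0141; adjusted p = 0.193 with an estimated correlation), and root tissue markers shifted upward (median 0.52, adjusted p = 0.0181; adjusted p = 0.193 with an estimated correlation). Both list calls were lost without cadmium-treated replicate 1 or untreated replicate 3, and the call of COR47 without any of the 6 arrays, with each array centred on its median or with the 25S level as a covariate. The call of GSTU18 was also lost in 6 other fits, among them those with quantile normalization and with all 24 arrays. Among the 3 root markers PYK10, a beta-glucosidase of root endoplasmic reticulum bodies, rose by 0.71, and EXPA18 and EXPA7 read 0.52 and 0.09. The alternative NADH dehydrogenase gene NDB2, on the oxidative stress list, rose by 1.50 ± 0.24 (adjusted p = 0.00623). Across probe sets, 372 rose and 517 fell, 889 in all, of which 194 and 248 changed at least 2-fold. The count was 514 and 466 without cadmium-treated replicates 2 and 3, and 436 and 428 without untreated replicates 1 and 2. It was 1270 with the 25S level as a covariate and 1095 on high arrays alone.

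The same treatment in mutant roots gives the response of plants that lack OASA1. AT5G06730, a class III peroxidase gene, rose by 4.51 ± 0.26 (SE) log2 units, from 4.87 ± 0.21 (SD, n = 3) to 9.38 ± 0.43 (adjusted p = 8.6e-06, limma). AT5G52750, of the heavy-metal-associated domain family, rose by 3.61 ± 0.28 (adjusted p = 4.6e-05), the lectin gene AT5G18470 by 3.16 ± 0.34 and the peroxidase gene PRX52 by 3.49 ± 0.48. GR1 rose by 1.79 ± 0.13 (adjusted p = 3.6e-05) and AT1G47400 by 1.38 ± 0.26 (adjusted p = 0.0121). COR27 fell by 3.54 ± 0.19 (adjusted p = 3.5e-06), while AT4G33980 fell by 1.19 ± 0.20 and the defensin gene PDF2.1 fell by 2.57 ± 0.26. BCAT4, an aminotransferase of aliphatic glucosinolate synthesis, fell by 2.38 ± 0.34 (adjusted p = 0.0027). All of these calls held without any single array, though that of AT1G47400 was lost when all 24 arrays shared a model. Of 3 sulfate assimilation genes, APS3 rose by 1.07 ± 0.26 (adjusted p = 0.0394), a call that held only without cadmium-treated replicate 2, while APS4 and SIR read -0.17 and -0.01. Oxidative stress markers shifted upward (5 of 5 members positive, median 0.17, adjusted p = 0.0256; adjusted p = 0.253 with an estimated correlation), a call lost without cadmium-treated replicate 1 or 3. Of its 5 members 2 rose, NDB2 by 1.01 and the zinc-finger gene STZ by 1.68; NDB2 held its call only without untreated replicate 3, and STZ lost it without any of the 6 arrays and with replicate as a block. A fit of the 6 arrays alone ended the calls of APS3 and NDB2, the fit of all 24 that of NDB2, and high arrays alone those of APS3, NDB2 and STZ. In this genotype 559 probe sets rose and 411 fell, 970 in all, of which 324 and 202 changed at least 2-fold. Between WT and mutant roots, 148 rises were shared against 9.14 by chance and 145 falls against 9.34, while 13 probe sets were called in opposite directions. Without untreated replicates 2 and 3 the count was 608 and 634. It was 1247 with the 25S level as a covariate and 578 on high arrays alone, where 282 rose and 296 fell.

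Under cadmium, mutant roots against WT roots show how the genotypes differ once treated. AT5G06730 was 3.94 ± 0.26 (SE) log2 units higher in the mutant, at 9.38 ± 0.43 (SD, n = 3) against 5.44 ± 0.52 (adjusted p = 7.9e-05, limma). AT5G18470 was higher by 3.27 ± 0.34 (adjusted p = 0.00174) and AT5G52750 by 2.18 ± 0.28 (adjusted p = 0.00439), and these 3 calls held without any single array. PDC2, a pyruvate decarboxylase gene, was higher by 2.3 ± 0.38 (adjusted p = 0.0154), a call lost without replicate 2 of either genotype. QQS was higher by 1.3 ± 0.23 (adjusted p = 0.0196), a call lost without mutant replicate 1 or 2 or WT replicate 2 or 3. XTH19, a xyloglucan-modifying enzyme of the cell wall, was lower, at -1.84 ± 0.34 (adjusted p = 0.0236), a call lost without any of the WT arrays. AT3G43960, of the papain-like cysteine protease family, was lower, at -1.54 ± 0.26 (adjusted p = 0.0159), a call lost without mutant replicate 2 or 3. The calls of XTH19, AT3G43960 and ATGSTF13 were also lost when only the 6 arrays were fitted, and those of QQS, XTH19 and ATGSTF13 on high arrays alone. Of 12 glutathione S-transferases 1 passed, ATGSTF13 at -0.84, lost without mutant replicate 2 or WT replicate 1 or 2; GSTU28 and GSTU25 read -1.34 and 1.04. Oxidative stress markers shifted upward (4 of 5 members positive, median 0.36, adjusted p = 0.048; adjusted p = 0.333 with an estimated correlation), with adjusted p = 0.16 when replicate was a block and from 0.0145 to 0.476 without single arrays. None of the 5 passed over all probe sets and 2 passed adjusted over the list alone; STZ read 1.59 and NDB2 0.71. That call was lost without mutant replicate 1 or 3 or WT replicate 1. Of the 3 named sulfate assimilation genes, APS3, APS4 and SIR read 0.13, 0.23 and 0.01, none past the threshold. Calls shared with untreated roots were 5 higher, against 0.45 by chance, and 3 lower, against 0.23, the unnamed probe set among the lower. A further 4 were called in opposite directions. Of the 81 untreated calls 40 (49.4%) had the same sign under cadmium, and the log2 differences of all probe sets correlated at 0.00. In all, 277 probe sets were higher in the mutant and 118 lower under cadmium, 395 together. With replicate as a block the count was 672, which is given here because residuals paired by replicate number correlated at 0.11 to 0.64. It was 250, 116 and 188 without mutant replicates 1, 2 and 3, and 223, 131 and 243 without WT replicates 1, 2 and 3; with the 25S level as a covariate it was 518, and 142 on high arrays alone.

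**Figure D2:**
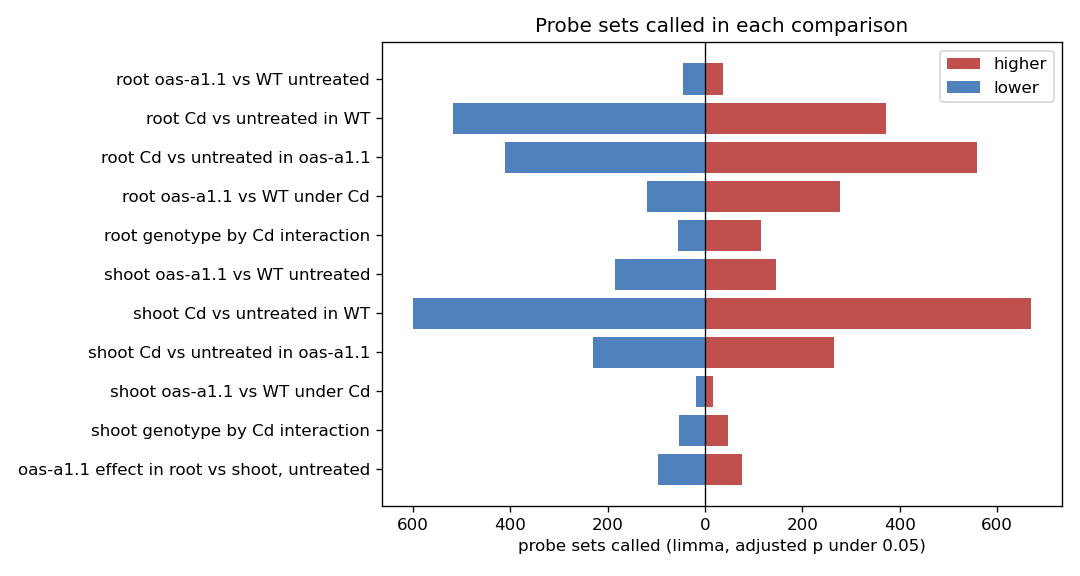
Number of probe sets past an adjusted p of 0.05 (limma, x axis) in each comparison (y axis), higher to the right of 0 and lower to the left. The largest total is cadmium in WT shoots, with 670 higher and 600 lower, and the smallest is mutant against WT shoots under cadmium, with 16 and 19.

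Whether cadmium acted differently in the mutant root was tested as the interaction of genotype and cadmium. Of the genes named, AT5G18470 differed most, by 4.12 ± 0.48 (SE) log2 units: it rose by 3.16 in the mutant and read 6.47 under cadmium in WT (adjusted p = 0.0119, limma, 3 arrays per group). AT5G06730 responded more in the mutant by 3.59 ± 0.37 (adjusted p = 0.00758) and AT5G52750 by 2.76 ± 0.39 (adjusted p = 0.0129). EXPB1, a beta-expansin of the cell wall, responded by -2.16 ± 0.29 relative to WT (adjusted p = 0.0129) and AT2G36690 by -2.04 ± 0.28 (adjusted p = 0.0129). These 5 calls held without any single array, and those of AT5G06730 and EXPB1 also on high arrays alone. PDC2 differed by 3.1 ± 0.54 (adjusted p = 0.0312), a call kept only without mutant untreated replicate 1, WT cadmium replicate 1 or WT untreated replicate 3. AT4G33980 differed by 1.73 ± 0.28 (adjusted p = 0.0253), a call lost without mutant cadmium replicate 2, mutant untreated replicate 2 or 3, WT cadmium replicate 2 or WT untreated replicate 1 or 2. COR27 differed by -0.03 ± 0.26 (adjusted p = 0.994) and GR1 by -0.38 ± 0.18 (adjusted p = 0.604). COR27 read 4.36 in WT and 4.03 in mutant roots under cadmium, near the 4.05 to 4.51 of the unnamed probe set on mutant arrays. A difference between its falls could therefore be hidden near background, which was not tested. No fixed gene list passed; the 12 glutathione S-transferases had a median of -0.11 (adjusted p = 0.196), with ATGSTF13 at -0.99, and the 8 heat shock genes a median of -0.35 (adjusted p = 0.196). The interaction passed for 170 probe sets, 115 with the higher response in the mutant and 55 with the lower. Higher here can mean a smaller fall: 46 of the 115 were called falls in WT. The absolute change was larger in the mutant for 97 of the 170. Of the 170, 80 were called in the WT response, 103 in the mutant response, 20 in both and 7 in neither. The count was 52 and 89 without mutant cadmium replicates 2 and 3, 53 and 49 without mutant untreated replicates 2 and 3, 79, 55 and 101 without WT cadmium replicates 1, 2 and 3, and 42 and 41 without WT untreated replicates 1 and 2. It was 208 with the 25S level as a covariate and 39 on high arrays alone, where 18 were higher and 21 lower.

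In untreated shoots, mutant against WT repeats the first question in the other organ. QQS rose by 2.02 ± 0.22 (SE) log2 units, from 7.01 ± 0.18 (SD, n = 3) in WT to 9.03 ± 0.13 in the mutant (adjusted p = 0.00298, limma). AT5G02230, of the haloacid dehalogenase-like hydrolase family, rose by 1.77 ± 0.20 (adjusted p = 0.00298). AT3G44450, an inhibitor of blue-light receptor signalling, fell by 1.50 ± 0.16, from 8.50 ± 0.16 to 7.01 ± 0.25 (adjusted p = 0.00266). These 3 calls held without any single array. AT3G23550, of the MATE efflux family, fell by 2.51 ± 0.53 (adjusted p = 0.0449), a call kept only without mutant replicate 1 or WT replicate 3 and lost with the 25S level as a covariate. PYE, a regulator of the iron deficiency response, fell by 0.79 ± 0.15 (adjusted p = 0.0352), a call likewise kept only without mutant replicate 1 or WT replicate 3 and lost with that covariate; BHLH101 of the same list read 0.04. Both calls were lost in a fit of the 6 arrays alone. No fixed list passed: the 12 glutathione S-transferases had a median of 0.06 (adjusted p = 0.388), with GSTU18 and GSTU20 both at 0.73 and not past the threshold. Of the 3 named sulfate assimilation genes, SIR read 0.28, APS3 -0.19 and APS4 -0.02, none past the threshold. In all, 146 probe sets were higher and 185 lower, 331 together, of which 64 and 62 changed at least 2-fold. The count was 563, 58 and 118 without mutant replicates 1, 2 and 3, and 45, 53 and 838 without WT replicates 1, 2 and 3. More were higher than lower without mutant replicate 2 (31 and 27) or WT replicate 1 (26 and 19) or 2 (28 and 25). On the second principal component of the shoot arrays WT replicate 3 lay at -10.22, between the other WT arrays at 24.45 and 30.61 and the mutant at -17.65 to -20.46. That component also follows the 25S level. Over all shoot arrays, those with a low level lay at 7.58 to 30.61 and those with a high level at -3.45 to -20.46. WT replicates 1 and 2 are low and the other untreated shoot arrays high, so genotype and that level are partly confounded here. The count was 278 with the 25S level as a covariate and 1 on high arrays alone.

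Cadmium in WT shoots shows the response of the normal shoot at 24 h. AT4G12980, of the cytochrome b561 family, rose by 3.16 ± 0.11 (SE) log2 units, from 5.11 ± 0.09 (SD, n = 3) to 8.27 ± 0.20 (adjusted p = 1.7e-07, limma). AT1G73600, a methyltransferase gene of phosphocholine synthesis, rose by 2.92 ± 0.23 and the sugar transporter gene SWEET13 by 2.19 ± 0.17. COR27 fell by 3.81 ± 0.18, from 9.07 ± 0.33 to 5.27 ± 0.17 (adjusted p = 2.0e-06), AT1G07050, of the CCT domain family, by 3.19 ± 0.22, the kinase gene AT3G59350 by 2.73 ± 0.21 and AT4G33980 by 1.23 ± 0.13. These calls held without any single array. Of the iron deficiency list, BHLH101, a regulator of iron uptake, rose by 2.2 ± 0.45 (adjusted p = 0.0175), a call lost without cadmium-treated replicate 3 or untreated replicate 1 or 2; PYE did not pass. AT1G47400 rose by 2.77 ± 0.68 (adjusted p = 0.0394), a call that held only without cadmium-treated replicate 1. Of 12 glutathione S-transferases 2 rose, GSTU16 by 0.96 ± 0.17 and GSTU20 by 1.28 ± 0.27, and none fell. GSTU20 lost its call without cadmium-treated replicate 3 or untreated replicate 1 or 2. GR1 rose by 0.77 ± 0.14 (adjusted p = 0.00904). Of 8 photosynthesis genes 1 rose, the antenna gene LHCB4.2, by 0.62 ± 0.10 (adjusted p = 0.00564), a call lost when all 24 arrays shared a model; RCA read 0.34. The defensin genes PDF1.2 and PDF1.2b rose by 1.65 ± 0.42 and 1.55 ± 0.36, calls lost without cadmium-treated replicate 1 or 3 or untreated replicate 1 or 2, and their probe sets may share targets. A fit of the 6 arrays alone ended the calls of BHLH101, AT1G47400, PDF1.2 and PDF1.2b. No fixed list passed; the lowest adjusted p, 0.0833, was shared by glutathione S-transferases, photosynthesis genes and the abscisic acid list. Across probe sets 670 rose and 600 fell, 1270 in all, of which 250 and 162 changed at least 2-fold. The count was 642 without cadmium-treated replicate 2, and 618 and 611 without untreated replicates 1 and 2; without untreated replicate 3, 719 rose and 976 fell. The count was 1692 with the 25S level as a covariate and 8 on high arrays alone.

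Cadmium in mutant shoots shows whether the shoot response persists without OASA1. PDF1.2b rose by 2.47 ± 0.36 (SE) log2 units, from 9.60 ± 0.54 (SD, n = 3) to 12.06 ± 0.36 (adjusted p = 0.00605, limma). AT4G12980 rose by 2.14 ± 0.11 (adjusted p = 1.1e-05), AT3G44450 by 2.2 ± 0.16 (adjusted p = 1.0e-04) and LHCB4.2 by 0.93 ± 0.10 (adjusted p = 0.00134). AT1G62480, of a calcium-binding protein family, fell by 2.01 ± 0.20, the glucosyltransferase gene UGT71B1 by 1.74 ± 0.19 and the glutaredoxin gene AT2G47880 by 1.92 ± 0.29. These calls held without any single array. PDF1.2 rose by 2.56 ± 0.42 (adjusted p = 0.0101), a call lost without cadmium-treated replicate 1. AT1G47400 rose by 3.31 ± 0.68 (adjusted p = 0.0322), a call that held only without cadmium-treated replicate 3 and was lost with the 25S level as a covariate. COR27 fell by 1.07 ± 0.18 (adjusted p = 0.0134) and AT4G33980 rose by 0.68 ± 0.13 (adjusted p = 0.0204). Both lost the call without cadmium-treated replicate 1 or 2, COR27 also without untreated replicate 2, and AT4G33980 also without untreated replicate 3 or with the 25S level as a covariate. Iron deficiency genes shifted upward (3 of 3 members positive, median 0.66, adjusted p = 0.0312; adjusted p = 0.192 with an estimated correlation). None of the 3 passed over all probe sets and 2 passed adjusted over the list alone; BHLH101 read 1.54, PYE 0.66 and AT3G13610 0.34. That call was lost without cadmium-treated replicate 1 or 3 or untreated replicate 1. Of 3 ascorbate and peroxide enzymes SAPX, the stromal ascorbate peroxidase, fell by 1.2 ± 0.25 (adjusted p = 0.0342), a call lost without any of the 6 arrays and with the 25S level as a covariate. Across probe sets 266 rose and 230 fell, 496 in all, of which 124 and 87 changed at least 2-fold. With WT shoots, 123 rises were shared against 7.84 by chance and 74 falls against 6.07, and 12 probe sets were called in opposite directions. The count was 227 and 236 without cadmium-treated replicates 1 and 2, and 297 and 250 without untreated replicates 2 and 3. It was 326 with the 25S level as a covariate and 2 on high arrays alone.

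**Figure D3:**
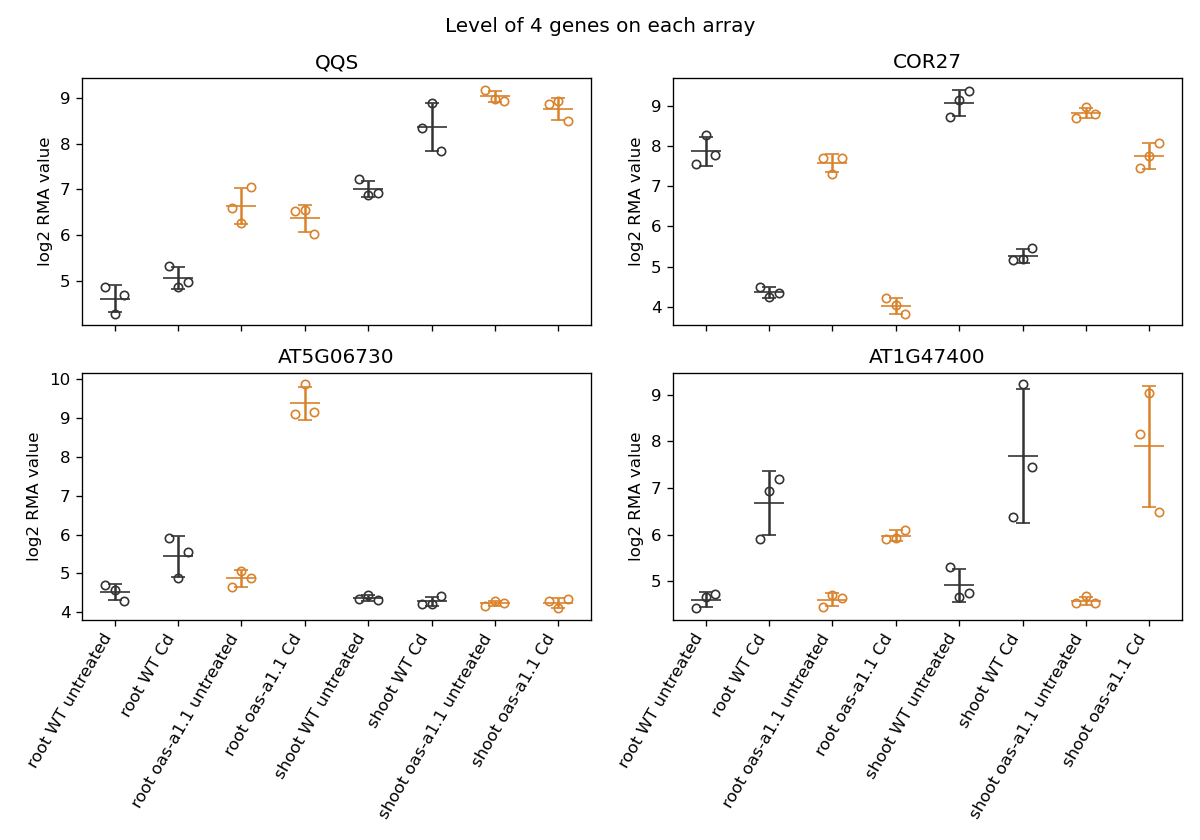
Log2 RMA value (y axis) of QQS, COR27, AT5G06730 and AT1G47400 on each array, by group (x axis), WT in black and oas-a1.1 in orange; open circles are arrays, the horizontal line is the mean and the bar is 1 SD (n = 3). COR27 reads 5.27 on average in WT shoots under cadmium and 7.75 in mutant shoots under cadmium, and AT5G06730 reads 9.38 in mutant roots under cadmium.

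Under cadmium, mutant and WT shoots differed at few probe sets. COR27 was 2.49 ± 0.18 (SE) log2 units higher in the mutant, at 7.75 ± 0.32 (SD, n = 3) against 5.27 ± 0.17 (adjusted p = 2.3e-04, limma). AT1G07050 was higher by 2.49 ± 0.22 (adjusted p = 5.5e-04), AT1G17665 by 1.37 ± 0.13 (adjusted p = 9.7e-04) and AT4G33980 by 1.16 ± 0.13 (adjusted p = 0.00408). AT4G12980 was lower, at -1.31 ± 0.11 (adjusted p = 5.5e-04). These 5 calls held without any single array. COR27 and AT4G33980 may move with the hour of harvest, and whether that hour differed between the genotypes was not tested. The glutaredoxin gene AT5G18600 was lower, at -0.91 ± 0.12 (adjusted p = 0.0152), a call lost without mutant replicate 1 or 3 or WT replicate 2, and when only the 6 arrays or all 24 were fitted. The abscisic acid and dehydration list shifted upward (3 of 3 members positive, median 0.90, adjusted p = 0.00608; adjusted p = 0.412 with an estimated correlation), a call lost without mutant replicate 2. Of its 3 members COR15A, a chloroplast protein of the cold response, passed at 2.16 ± 0.35 (adjusted p = 0.0495), but held its call only without WT replicate 1 and lost it with the 25S level as a covariate, a replicate block, quantile normalization or a fit of the 6 arrays. LTI30 read 0.90 and COR47 0.17. Of the 3 named sulfate assimilation genes, APS4 read 0.19, SIR 0.13 and APS3 -0.03, none past the threshold, and QQS read 0.40 (adjusted p = 0.656, limma). Calls shared with untreated shoots were 1 higher, against 0.10 by chance, and 2 lower, against 0.15, the unnamed probe set among the lower. A further 2 were called in opposite directions. Of the 331 untreated calls 180 (54.4%) had the same sign under cadmium, and the log2 differences of all probe sets correlated at 0.00. In all, 16 probe sets were higher and 19 lower under cadmium, 35 together. The count was 14, 15 and 18 without mutant replicates 1, 2 and 3, and 23 and 13 without WT replicates 1 and 2. More were higher than lower in each of these 5 (8 and 6, 11 and 4, 10 and 8, 12 and 11, 9 and 4), against 11 and 20 without WT replicate 3, so the balance is not settled. The count was 41 with the 25S level as a covariate and 1 on high arrays alone.

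The interaction in shoots tests whether cadmium acted differently in the mutant. The mean 25S level was 7.23 untreated and 7.66 under cadmium in WT, against 9.31 and 6.34 in the mutant. This contrast is therefore partly confounded with that level. COR27 fell less in the mutant by 2.74 ± 0.26 (SE) log2 units (adjusted p = 0.00193, limma, 3 arrays per group), and AT4G33980 differed by 1.92 ± 0.18 (adjusted p = 0.00193). AT1G17665 differed by 2.49 ± 0.18 (adjusted p = 5.7e-04), AT1G07050 by 2.50 ± 0.30 and AT3G59350 by 2.45 ± 0.30. AT5G19120, of the aspartyl protease family, differed by -2.30 ± 0.27 (adjusted p = 0.00782) and AT5G02230 by -2.14 ± 0.28 (adjusted p = 0.012). These 7 calls held without any single array. A difference in the hour of harvest between groups may also move COR27 and AT4G33980, which was not tested here. The glutaredoxin gene AT3G62950 differed by -2.60 ± 0.41 (adjusted p = 0.0233), a call kept only without mutant cadmium replicate 3, mutant untreated replicate 1 or 3, WT cadmium replicate 1 or WT untreated replicate 3, and lost with the 25S level as a covariate. QQS differed by -1.62 (adjusted p = 0.0561), which did not pass. No fixed list passed; the glutathione S-transferases had a median of -0.08 (adjusted p = 0.208) and the abscisic acid list a median of 1.61 (adjusted p = 0.251), with COR15A at 1.61 and LTI30 at 1.88. The interaction passed for 101 probe sets, 47 higher in the mutant response and 54 lower. Of the 47, 34 were called falls in WT, and the absolute change was larger in the mutant for 31 of the 101. Of the 101, 80 were called in the WT response, 37 in the mutant response, 19 in both and 3 in neither. The count was 25 and 52 without mutant cadmium replicates 1 and 2, 51 without mutant untreated replicate 2, 41 without WT cadmium replicate 2, and 23, 26 and 607 without WT untreated replicates 1, 2 and 3. More were higher than lower without mutant cadmium replicate 1 (16 and 9) or 2 (28 and 24), WT cadmium replicate 1 (55 and 48) or WT untreated replicate 1 (14 and 9), 2 (18 and 8) or 3 (409 and 198), so the balance of the 101 is not settled. The count was 75 with the 25S level as a covariate and 0 of 22746 on high arrays alone by limma, with 1530 at an unadjusted p under 0.05 in that fit.

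The effect of the mutation in untreated roots was set against that in untreated shoots. AT5G19120 differed by -2.76 ± 0.35 (SE) log2 units, lower in mutant roots than in WT roots relative to the shoot difference (adjusted p = 7.3e-04, limma, 3 arrays per group). AT2G36690 differed by 2.12 ± 0.25 (adjusted p = 3.2e-04), AT5G02230 by -2.47 ± 0.35 (adjusted p = 0.00125) and AT5G62140 by -1.67. These 4 calls held without any single array. QQS rose by 2.02 in both organs, but it averaged only 4.62 in WT roots, so the root rise may be understated. Of the probe sets called in both organs, 4 were higher in both against 0.24 by chance, 2 were lower in both against 0.36, and 2 went in opposite directions. The difference between organs passed for 173 probe sets, 77 higher and 96 lower in root than in shoot. The count was 95 and 98 without mutant root replicates 2 and 3, 82 without WT root replicate 2, 87 without mutant shoot replicate 2, and 71, 85 and 394 without WT shoot replicates 1, 2 and 3, the last with 244 higher and 150 lower. The count was 191 with the 25S level as a covariate and 12 on high arrays alone. Cadmium responses were not compared between organs, since the hours of treatment differed.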

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

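The differences between effects in this part were each tested directly, as an interaction or as a difference between organs, and planned before the data were examined, except that the values of AT4G33980, AT1G76590 and AT1G30820 in roots, of AT3G44450, AT4G12980 and AT2G41250 in shoots, and of AT3G15650, AT3G44450, AT5G02230, AT5G19120, AT5G62140 and AT2G36690 between organs were picked after these genes had been named elsewhere. The cadmium effects on COR27 and AT4G33980, the shoot counts and the plastid-encoded median are not such differences, and were noticed in the results. Of the tests of explanations, those on harvest time and on the cadmium response, and the matched leave-outs of shoot counts, were chosen after the result was seen.

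In roots the response to cadmium differed between genotypes at 170 probe sets. The mutant response was higher for AT5G18470 by 4.12, AT5G06730 by 3.59, PDC2 by 3.1, AT1G05575 by 2.87, AT5G52750 by 2.76, AT5G28610 by 2.49, AT1G30820 by 2.03, AT1G76590 by 1.96 and AT4G33980 by 1.73 log2 units. It was lower for AT4G25250 at -3.67, XTH19 at -2.68, EXPB1 at -2.16, AT2G36690 at -2.04, AT1G73620 at -1.75 and AT3G46270 at -1.57. A higher response can be a smaller fall: of 115 probe sets with the higher mutant response, 46 were called falls in WT. AT2G36690 was already higher, and AT4G33980 and AT1G76590 already lower, in untreated mutant roots than in WT. Without any single array the calls of AT5G18470, AT5G06730, AT5G52750, AT1G30820, EXPB1 and AT2G36690 held. The other 9 were lost in 6 to 11 of the 12 leave-outs each.

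In shoots it differed at 101 probe sets. The mutant response was higher for COR27 by 2.74, AT1G07050 by 2.50, AT1G17665 by 2.49, AT3G59350 by 2.45, AT1G78410 by 2.32, AT4G33980 by 1.92 and AT3G44450 by 1.47. It was lower for AT3G62950 at -2.60, AT5G19120 at -2.30, AT5G02230 at -2.14, AT4G33666 at -2.08, AT3G26510 at -1.95, AT4G14930 at -1.79, AT2G41250 at -1.69 and AT4G12980 at -1.02. Of 47 probe sets with the higher mutant response, 34 were called falls in WT. AT5G02230 was already higher, and AT3G44450 already lower, in untreated mutant shoots than in WT. Without any single array the calls of COR27, AT1G07050, AT1G17665, AT3G59350, AT4G33980, AT5G19120 and AT5G02230 held, and the other 8 were lost in 3 to 10 of the 12 leave-outs each.

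Between untreated roots and shoots the effect of the mutation differed at 173 probe sets. The root effect was higher for AT2G36690 by 2.12, AT3G15650 by 1.63 and AT3G44450 by 1.52, and lower for AT5G19120 at -2.76, AT5G02230 at -2.47 and AT5G62140 at -1.67. The calls of AT3G15650 and AT3G44450 were lost in 9 and 7 of the 12 leave-outs.

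COR27 and AT4G33980 were lower under cadmium in both organs of WT. With the 25S level as a covariate 4 of 4 values stayed below -1 and called, COR27 at -3.57 in roots and -3.84 in shoots, which argues against that level as the cause. A harvest at another time of day may move both genes, since untreated and treated plants could have been taken at different hours. The 4 other clock-regulated genes measured had a median absolute change of 0.40 in WT roots, where AT1G69570 rose by 0.60 and GI read -0.10. In WT shoots that median was 0.45. There AT3G44450 rose by 0.72 (adjusted p = 0.0225, limma), and the rest of these genes did not pass. AT3G44450 was also called higher under cadmium in mutant shoots. Harvest time therefore stays open. A cadmium response stays open too. COR27 and AT4G33980 were both called lower in 3 of 4 cadmium comparisons. The exception was mutant shoots, where AT4G33980 rose by 0.68.

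Mutant and WT shoots differed at 331 probe sets untreated and at 35 under cadmium, a ratio of 9.46. With the 25S level as a covariate the ratio was 6.78, which argues against that level as the whole cause. The measure set beforehand, the lowest untreated count without 1 array over the highest under cadmium, gave 45 against 31, a ratio of 1.45, but leaves out different arrays; with an array of the same genotype and number left out of each contrast, which replaced it, the ratio ran from 1.96, 45 against 23 without WT replicate 1, to 40.21, 563 against 14 without mutant replicate 1. With 1 untreated array left out of a fit of both contrasts it was 1.50 without WT replicate 1, 1.61 without WT replicate 2 and 17.83 without WT replicate 3, where the untreated contrast alone lost an array. The size of the gap therefore depends on single untreated arrays, which may carry part of it. WT replicates 1 and 2 have a low 25S level and the other untreated shoot arrays a high one, so that level may carry part of it too. An effect of cadmium on the genotype difference stays open.

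The plastid-encoded genes read higher in untreated mutant shoots, with a median of 0.29 over 69 probe sets and 57 of them positive, but 0 of the 69 passed by limma, and the adjusted p of 3.7e-06 by camera was 0.933 with an estimated correlation and 0.685 by fry. With the 25S level as a covariate the median was 0.29, which argues against that level. The lowest median without 1 array was 0.17, without WT replicate 1, and it was 0.18 without WT replicate 3 and 0.40 without WT replicate 2. A part played by single WT arrays may therefore remain, and the mutation itself, which the design names, stays open.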

How the results depend on the processing

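With 3 arrays per group the counts depended on the model and on single arrays. Of 345 named values 185 were called, and none of these changed sign in 3705 alternative values, 983 of which lost the call. Many called values were picked because their groups did not overlap, so leaving out an array could not change their sign. The 160 values that were not called changed sign in 183 of 3204 and gained a call in 71. Of the 185 called values 94 kept the call in every leave-out and 162 with the 25S level as a covariate. The settings on 25S level, those without a replicate number in all groups, and list leave-outs were chosen after the values were seen. Only counts that moved by more than 1.5 times are given, and the cause was not tested. A model of all 24 arrays called 246 probe sets for the mutant in untreated roots in place of 81, 1409 for cadmium in WT roots in place of 889, 689 between genotypes in roots under cadmium in place of 395, 441 for the root interaction in place of 170, 515 for the mutant in untreated shoots in place of 331, 88 between genotypes in shoots under cadmium in place of 35 and 278 for the shoot interaction in place of 101. A model of the compared arrays alone called 36 for the mutant in untreated roots, 152 in roots under cadmium, 64 in untreated shoots and, on the 12 untreated arrays, 101 between organs in place of 173. Array weights, in the order of the report, called 561, 1837, 1952, 727 and 828 in roots, 1850, 2926, 1259, 228 and 1177 in shoots and 2176 between organs. With replicate as a block the counts were 174, 1547, 1516, 672 and 385 in roots, 665 for the mutant in untreated shoots, 768 for cadmium in mutant shoots, 227 for the shoot interaction and 444 between organs. The upper 60% of probe sets gave 144 for the mutant in untreated roots, 263 for the root interaction and 160 for the shoot interaction. Median centring gave 162 for the shoot interaction, and a trended and robust prior 55 between genotypes in shoots under cadmium. Arrays with a high 25S level gave 124 for the mutant in untreated roots, 578 for cadmium in mutant roots, 142 in roots under cadmium, 39 for the root interaction, 1, 8, 2, 1 and 0 by limma for the 5 shoot comparisons (1530 at an unadjusted p under 0.05 for the interaction in that fit) and 12 between organs; with single arrays left in 2 shoot groups, the shoot and organ counts say nothing about stability. The 25S level as a covariate gave 326 for cadmium in mutant shoots in place of 496.

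Leaving replicate 1 out of all groups called 7, 418, 511, 97 and 2 probe sets in roots, in the order of the report, 53, 280, 107, 4 and 0 in shoots and 35 between organs. Leaving out replicate 2 called 2, 115, 115, 2 and 0 in roots, 1, 104, 58, 3 and 2 in shoots and 6 between organs. Leaving out replicate 3 called 1, 329, 394, 72 and 10 in roots, 999, 17 and 537 for the mutant untreated, the mutant under cadmium and the interaction in shoots, and 264 between organs. In the fits with a count of 0 by limma, 984 probe sets had an unadjusted p under 0.05 for the root interaction without replicate 2 and 1669 for the shoot interaction without replicate 1. Without any single array the count ranged from 17 to 138 for the mutant in untreated roots, 428 to 829 for cadmium in WT roots, 608 to 710 for cadmium in mutant roots, 116 to 250 in roots under cadmium and 41 to 243 for the root interaction. The ranges were 45 to 838 for the mutant in untreated shoots, 611 to 1695 for cadmium in WT shoots, 227 to 574 for cadmium in mutant shoots, 13 to 31 in shoots under cadmium, 23 to 607 for the shoot interaction and 71 to 394 between organs. The arrays that moved a count by more than 1.5 times are named in the report. Whether more probe sets were higher or lower turned in 5 of 6 leave-outs for the mutant in untreated roots, all but WT replicate 3, and in 5 of 6 in shoots under cadmium, again all but WT replicate 3. It turned without mutant replicate 2 or WT replicate 1 or 2 in untreated shoots, without untreated replicate 3 for cadmium in WT shoots, without WT shoot replicate 3 between organs, and in 6 of 12 leave-outs for the shoot interaction. Of 10 gene list calls by camera, 0 passed with an estimated correlation, and fry called 6, of which 5 were shared.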

Other observations

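In WT roots under cadmium 6 of 47 UDP-glycosyltransferases rose, among them UGT72E1 by 1.35 ± 0.29 (SE), and the other 41 did not pass. The median was 0.23, against -0.04 in mutant roots. In WT, camera gave the family an adjusted p of 1.6e-04, held without any single array, but the adjusted p was 0.827 with an estimated correlation and 0.232 by fry. UGT72E1 itself kept its call only without untreated replicate 3. Camera at the fixed correlation also called the family's interaction of genotype and cadmium, kept in 11 of 12 leave-outs. The families and their tests were fixed after the gene names had been seen but before any test. Of 9 xyloglucan endotransglucosylases, enzymes that remodel cell wall xyloglucan, 1 was lower in mutant than in WT roots under cadmium and 8 did not pass, with a median of -0.32 (adjusted p = 0.00125; adjusted p = 0.444 with an estimated correlation). Their cadmium response differed by a median of -1.14 (adjusted p = 0.00608 by camera, and 0.593 with an estimated correlation). The family median was 0.55 higher in untreated mutant roots than in WT. Under cadmium it changed by 0.55 in WT and by -0.42 in mutant roots. Part of the differing response thus lay in the untreated genotype difference. XTH19 rose by 1.70 under cadmium in WT roots, a call lost without cadmium-treated replicate 1 or 3 or untreated replicate 1 or 2. Of 22 trichome birefringence-like genes, which act in cell wall acetylation, 2 were lower and 20 did not pass, with a median of -0.20 (adjusted p = 0.00178; adjusted p = 0.444 with an estimated correlation), a call lost without WT replicate 1; TBL41 read -0.91 ± 0.13. Of 6 WRKY transcription factors 2 were higher in mutant roots under cadmium and 4 did not pass, with a median of 0.33 (adjusted p = 0.00178; adjusted p = 0.444 with an estimated correlation). WRKY53 rose by 2.28 ± 0.27 under cadmium in mutant roots, a call held without any single array, and its interaction of 2.08 kept its call only without WT untreated replicate 3.

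In WT shoots under cadmium 2 of 8 autophagy genes rose and 6 did not pass, with a median of 0.35 (adjusted p = 0.00764; adjusted p = 0.417 with an estimated correlation), a call lost without cadmium-treated replicate 3. ATG8E rose by 1.16 ± 0.23, a call lost without cadmium-treated replicate 2. Between mutant and WT shoots under cadmium the same family had a median of -0.36 (adjusted p = 3.8e-04; adjusted p = 0.456 with an estimated correlation); 0 of the 8 passed by limma over all probe sets and 5 passed adjusted over the list alone. Of 7 tubulins in WT shoots 3 fell and 4 did not pass, 2 of the 7 reading higher, with a median of -0.30 (adjusted p = 0.00764; adjusted p = 0.417 with an estimated correlation), a call lost without cadmium-treated or untreated replicate 3; TUB9 fell by 1.25 ± 0.11. Of 5 methionine sulfoxide reductases, which repair oxidised methionine, 1 rose in mutant shoots under cadmium and 4 did not pass, with a median of 0.56 (adjusted p = 0.0181; adjusted p = 0.447 with an estimated correlation), a call lost without cadmium-treated replicate 2 or 3. MSRB6 rose by 2.12 ± 0.34, a call held without any single array. Plastid-encoded genes had a median of -0.41 in mutant shoots under cadmium, with 1 of 69 positive and 1 past the threshold (adjusted p = 1.8e-16; adjusted p = 0.447 with an estimated correlation), and -0.27 in mutant roots (adjusted p = 1.6e-04; adjusted p = 0.707 with an estimated correlation), the latter call lost without cadmium-treated replicate 1. In WT the medians were 0.11 in shoots and -0.17 in roots, neither called. The 25S level was lower in cadmium-treated than in untreated mutant shoots, 6.34 against 9.31 on average; with it as a covariate the medians were -0.53 in mutant shoots and -0.26 in mutant roots. On arrays with a high 25S level, which leave 1 cadmium-treated mutant shoot array, they were -0.39 and -0.13. Both settings were chosen after the values were seen, and the 25S level may carry part of the root value. Their response in shoots differed between genotypes by a median of -0.61 (adjusted p = 2.8e-15; adjusted p = 0.478 with an estimated correlation), held without any single array. No list or family called by camera changed the sign of its median under median centring or quantile normalization.

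The root interaction count was 170, against 385 with replicate as a block and 39 on arrays with a high 25S level, so the breadth of the difference between genotypes may be smaller or larger than the first count. QQS was higher by 2.02 in both organs of the untreated mutant, though its low value in WT roots, 4.62, may understate the root difference. Under cadmium its difference was 1.3 in roots, a call lost without 4 of the 6 arrays, and 0.40 in shoots (adjusted p = 0.656), where it did not separate the genotypes. Whether the untreated difference comes from the loss of OASA1 or from another change in the line was not tested.

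Other splits of the same arrays were counted. For the 8 comparisons of 3 against 3 arrays there were 10 splits, too few for a share under 0.05, and 1 of the 10 gave as many calls in each. In roots the real counts were 81, 889, 970 and 395, in the order of the report, and the highest others were 0, 39, 0 and 0 by limma. In shoots they were 331, 1270, 496 and 35, against 24, 0, 0 and 1. Each other split mixes arrays of the 2 groups, so any difference between them widens the spread in the model. Low counts there were thus likely in advance and exclude neither chance nor a structure of the samples. For the root interaction 2 of 100 splits gave as many, with a highest other of 4222, far above the real 170. That split had the largest interaction contrast of the 100 on both the first and second principal component of the root arrays, 47.68 and 67.87 against 5.74 and 31.81 for the real one, and its many calls point to a structure of the samples. Over the 100 splits calls correlated with these contrasts at only 0.08 and 0.11 (Spearman), and a split with 41.05 on the second component gave 46 calls. In every root group the first component rose from replicate 1 to 3, as from -37.82 to -13.87 in untreated WT. The interquartile range of log2 values fell, from 2.81 to 2.89 on replicate 1 to 2.37 to 2.48 on replicate 3. The split with 4222 calls set replicate 1 of every root group against replicate 3 of every root group. Replicate order is thus part of that structure, and the main root model has no term for it. That split was not fitted with replicate as a block, so how many of the 4222 calls replicate order gave was not tested. The blocked count of the real interaction was 385. For the shoot interaction 1 of 100 splits gave as many, 101 against a highest other of 63, and for the difference between organs 2 of 100, 173 against 177. The shoot split with 63 calls had the largest contrast on the second principal component, 54.17 against 45.76 for the real one. In these 3 cases the share was under 0.05. The splits swapped genotype within a treatment or organ, so they also broke genotype differences that are not interactions. They therefore cannot exclude chance for the interaction alone, nor a structure of the samples. The numbers of called gene lists were less separated. In untreated roots 5 of 10 splits gave as many list calls (2, highest other 4), for cadmium in WT roots 1 (4, highest other 1), for cadmium in mutant roots 8 (1, highest other 4) and for roots under cadmium 4 (1, highest other 2). In shoots 10 of 10 gave as many for the untreated mutant (0, highest other 2) and for cadmium in WT (0, highest other 2), 4 for cadmium in the mutant (1, highest other 2) and 3 under cadmium (1, highest other 1). For both interactions 0 lists were called by camera or by fry, 100 of 100 splits gave as many, and the highest others were 5 in roots and 3 in shoots. Where the real count is 0 every split gives as many, so those 4 comparisons test nothing.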
